A study of Mus musculus with 48 samples.

How the data were processed

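The series holds ChIP-seq of RAW264.7 cells for 6 targets in 47 libraries and 1 input sample, for which no peak list was used here. Per the labels' protocols, cells were kept in vehicle (0.1% ethanol) or 1 µM dexamethasone for 16 h and then received LPS (given in the labels as 100 ng per µl) for 3 h. Histone, Setd1a and Cxxc1 libraries were fixed for 10 min in 1% formaldehyde, GR libraries also for 30 min in 2 mM disuccinimidyl glutarate. Drosophila chromatin was added as a spike-in to the histone libraries per the labels; whether the deposited lists were scaled by it is not given in the sources used here. Groups and replicate numbers come from the sample titles.

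The authors made 1 peak list per library at an FDR of 0.05, per the file names, without pooling replicates. The submitters' processing notes name BWA 0.7.13, Picard 2.0.1 and MACS2 2.1.1.20160309 and the builds mm10 and GRCm38. Each deposited list gives for every peak its position and width in bp, a whole-number pileup signal, a fold enrichment ratio over background, −log10 p and −log10 q values, per the file headers and the values, and the nearest gene with its distance and the peak's place relative to it, in the authors' own annotation. The control used in calling and the version of that annotation are not given in the sources used here. The peak scores are the authors' and were used only to describe, rank or filter peaks within a list. Coordinates are in mm10, counted from 1. The gene table used for TSS positions and gene coordinates was RefSeq for GRCm38.p6, the same build. No read counts were used, so the depth is unknown. No sample in these groups shared more than 11 identical peaks with another of its group.

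A library with more covered genome covers more of every set of sites. The main results on genes and on GR sites therefore used lists of equal covered length per mark, in which peaks were kept in order of −log10 q until they covered what the shortest list of the mark covered (28.4 Mb for H3K4me1, 50.2 Mb for H3K4me2 and 40.0 Mb for H3K4me3). This assumes that genotype and treatment leave the total unchanged, so a change shared by the whole genome cannot show in these lists. The lowest −log10 q kept ran from 1.32 to 12.8 for H3K4me1, 1.31 to 138 for H3K4me2 and 1.33 to 62.7 for H3K4me3. It was higher in longer lists as a rule: 11.3 to 12.8 in wild-type Dex+LPS H3K4me1 libraries, against 3.10 to 5.47 in wild-type LPS ones. A gene with weak peaks can therefore be listed at 0 bp in 1 group only. The covered length itself was compared on the lists as deposited.

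Covered bp per gene, over the peaks that the authors' annotation places nearest to it, were analysed as log2(bp + 500) with limma 3.58.1 (trend) in R 4.3.3, with 4 group means per mark and Benjamini-Hochberg adjustment at 0.05 over genes with a mean of at least 500 bp (7452 genes for H3K4me1, 12277 for H3K4me2, 11977 for H3K4me3). A log2 change on this scale understates the change of genes with little covered length, and a gene without a peak is listed at 0 bp, which with no counts behind it need not mean absence of the mark. Each peak gives its whole width to 1 gene, so peaks that merge or shift can move all their bp to a neighbouring gene. Treatment was averaged over genotypes, genotype over treatments, and the interaction is the difference of the treatment effect between genotypes. Covered length and the share of GR sites were compared by exact two-sided permutation of the labels within the other factor. GR sites are peaks of GR replicate 1 that overlap a peak of replicate 2 or 3 by at least 1 bp. Shares of sites carry 95% Wilson intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

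Gene lists were tested with camera from limma with its preset correlation of 0.01 and again with an estimated one, adjusted over the 9 lists. These were glucocorticoid-induced (40 genes), inflammatory (40), interferon-stimulated (30), macrophage identity (30), and members of H3K4 methyltransferase complexes with H3K4 demethylases (26). The others were cell cycle (32), housekeeping (20), lymphoid (20) and non-haematopoietic genes (24). Of the lists that passed, only the H3K4me1 rise of glucocorticoid-induced genes held with an estimated correlation. Named genes followed a rule set before the data were examined, as were the lists, the tests and most of the other settings tried: 12 genes named throughout, up to 6 members of each list past the threshold by adjusted p, and the 5 largest gains and 5 largest losses past it whose libraries did not overlap between groups within either stratum. Of the genes this rule takes, 3 are not reported here; they remain in the counts and the tests. For peaks, the 6 with the largest −log10 q found in every library of the target were named.

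On simulated data in which 200 genes were changed in these libraries, limma recovered 14.9, 43.3 and 78.8% of genes changed by 0.5, 1 and 2 (log2) in the H3K4me1 treatment comparison of 7452 genes, and 13.4, 35.8 and 71.2% in the genotype comparison. For H3K4me2, 12277 genes, the shares were 37.3, 56.7 and 63.6% for treatment and 44.8, 56.7 and 62.1% for genotype. For H3K4me3, 11977 genes, they were 82.1, 95.5 and 93.9% for treatment and 85.1, 91.0 and 93.9% for genotype. Between 3 and 14 unchanged genes were called in each. The simulation drew each gene and library independently, with no effect shared by a library and no uneven cut of the lists. False calls in the real lists may therefore be more frequent. Other splits of the real H3K4me1 libraries by treatment called a median of 0 and up to 347 genes. The split with 347 exchanged only Setd1aDel/+ LPS replicate 1 and Setd1aDel/+ Dex+LPS replicate 3. It kept all other treatment labels, so its calls do not measure false ones.

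The other settings tried, fixed before the files were opened, were a −log10 q of at least 5, peak numbers for covered length, the lists as deposited, lists of equal peak number, pseudocounts of 100 and 2000 bp, no filter on covered length, peaks within 50 kb of the TSS, other definitions and overlaps of GR sites, each genotype or treatment alone, library-number series, the replicate block, an estimated correlation, and leaving out each library in turn. Added after the data were seen were quantile normalization of the lists as deposited, leaving out chromosome 1, the replicate block in wild-type H3K4me1 libraries alone, the covered length interaction without single libraries, the pileup limit of 1000, the comparison with distal H3K4me2 windows, the tests of genes nearest to GR sites, and the overlap of genes between marks.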

Results

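RAW264.7 is a mouse macrophage line from a male Balb/c animal. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped the glucocorticoid receptor (GR) and 3 methylation states of histone H3 lysine 4: H3K4me1, typical of enhancers, H3K4me2, and H3K4me3, typical of active promoters. It also mapped the H3K4 methyltransferase Setd1a and Cxxc1, the CpG-binding subunit of the same methyltransferase complex. Cells were wild type or carried 1 loss-of-function allele of Setd1a (Setd1aDel/+). They received lipopolysaccharide (LPS), a bacterial activator of macrophages, for 3 h, after 16 h in vehicle (LPS group) or in 1 µM of dexamethasone, a synthetic glucocorticoid (Dex+LPS group). H3K4me1 had 3 libraries in each of the 4 groups. H3K4me2 had 2 wild-type LPS, 5 wild-type Dex+LPS, 3 Setd1aDel/+ LPS and 3 Setd1aDel/+ Dex+LPS libraries, and H3K4me3 had 2, 2, 3 and 4 in the same order. GR was mapped in 3 wild-type Dex+LPS libraries, and Setd1a and Cxxc1 in 2 wild-type libraries per treatment. The number of reads is not given in the sources used here, so the size of each peak list stands in for depth. It ran from 47959 to 110422 peaks for H3K4me1, 37283 to 65302 for H3K4me2, 23576 to 34999 for H3K4me3. It was 498 to 6916 for GR, 1109 to 7007 for Setd1a and 2147 to 13224 for Cxxc1. Peaks of replicates shared 0.853 to 0.90 of their joint covered length for H3K4me3, 0.645 to 0.845 for H3K4me2 and 0.372 to 0.580 for H3K4me1. For the other targets the share was 0.191 to 0.204 for Cxxc1, 0.139 to 0.242 for Setd1a and 0.0353 to 0.219 for GR. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

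GR peaks in cells given dexamethasone and LPS lay mostly away from promoters. Of the 6916 peaks of replicate 1, 1519 recurred in replicate 2 or 3 (498 and 1697 peaks, of which 91.2% and 89.0% lay in replicate 1) and are called GR sites here. Their median distance to a transcription start site (TSS) was 25478 bp, 107 (7.04%) lay within 1 kb of one, and 1202 genes were nearest to at least 1 site. Sites found in all 3 libraries numbered 396. By the authors' −log10 q, the strongest of these lay 2348134 bp from its nearest gene, Lrrc4c (chromosome 2, 98666303-98667318, mm10, pileup 54580). Others lay at 3 places near Mir101c (chromosome 9, 3023483-3025147, 3000291-3004771 and 3006401-3008054). The next lay 184349 bp from Gm5458 (chromosome 14, 19416928-19418238, called the Gm5458 region here) and 14932 bp from Gm16325 (chromosome 3, 146656864-146658583, authors' fold enrichment 186). The Gm5458 region carried a peak in all 47 libraries of the series, and the Lrrc4c and Mir101c regions in 27, with pileups far above their fold enrichments of 6.45 to 4.04. Among sites with a pileup up to 1000, a limit set after these values were seen, the strongest after Gm16325 lay inside Ccnd3, the cyclin D3 gene (chromosome 17, 47507447-47508892, fold 126), 4536 bp upstream of Klf9, a glucocorticoid-induced transcription factor (chromosome 19, 23134079-23136690, fold 85.9). The others lay far from 4921513I03Rik (chromosome 10) and Dock10 (chromosome 1) and inside Cdk6, a cell-cycle kinase (chromosome 5, 3501215-3503811, fold 63.8).

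The genome covered by H3K4me1 peaks was larger with dexamethasone in wild-type cells, 69.0 ± 1.81 Mb against 37.8 ± 6.85 Mb (SD, n = 3 each), while Setd1aDel/+ libraries held 45.4 ± 21.9 Mb against 38.2 ± 9.10 Mb. Averaged over genotypes the difference was +19.2 Mb (57.2 against 38.0 Mb; stratified exact permutation test, two-sided, p = 0.04, 0.12 after Benjamini-Hochberg adjustment over the 6 comparisons of covered length). The difference between genotypes in this response was −24.0 Mb and was not past the threshold (p = 0.215 by exact permutation). Replicate 2 of Setd1aDel/+ Dex+LPS (70.7 Mb) carried its group mean: without it the other 2 libraries averaged 32.7 Mb, below LPS, and the difference was −36.6 Mb. Within series of library numbers, which the sample titles or file names carry, the treatment difference was +17.9 Mb (p = 0.0972 by the same exact test).

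H3K4me3 covered more of the genome in Setd1aDel/+ cells, 46.8 Mb against 41.8 Mb in wild type. The difference of +4.96 Mb had p = 0.00667, the smallest that the 150 exact permutations of these 11 libraries can give, and 0.04 after adjustment. Group means were 41.2 ± 1.70 Mb in wild-type LPS (n = 2), 42.4 ± 2.13 Mb in wild-type Dex+LPS (n = 2), 46.2 ± 1.47 Mb in Setd1aDel/+ LPS (n = 3) and 47.4 ± 0.862 Mb in Setd1aDel/+ Dex+LPS libraries (n = 4). After adjustment no other comparison of covered length passed, and the remaining ones had these unadjusted exact permutation p: +1.16 Mb for H3K4me3 with dexamethasone (p = 0.262), +12.9 Mb for H3K4me2 with dexamethasone (p = 0.0643), +11.3 Mb for H3K4me2 (p = 0.116) and −11.6 Mb for H3K4me1 (p = 0.235) in Setd1aDel/+ cells. Within library-number series the H3K4me3 genotype difference was +4.99 Mb (p = 0.0278, the smallest that its 36 exact permutations can give, and 0.167 after adjustment), so within series it did not pass.

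**Figure D1:**
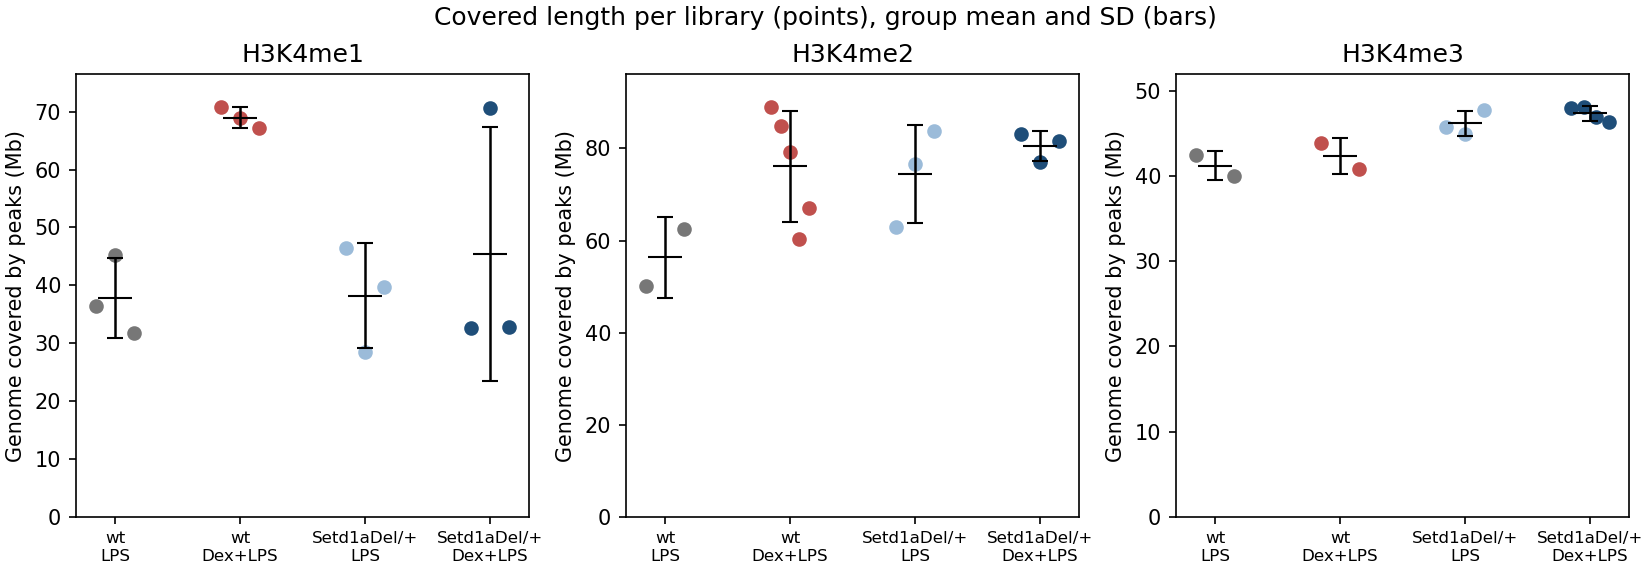
Genome covered by the peaks of each library in Mb (points) for H3K4me1, H3K4me2 and H3K4me3, by genotype and treatment, with the group mean and SD (bars). H3K4me1 libraries of wild-type Dex+LPS cells lie between 67.2 and 70.8 Mb, and H3K4me3 libraries of Setd1aDel/+ cells between 45.0 and 48.1 Mb.

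How dexamethasone before LPS alters H3K4 methylation at genes was examined next. H3K4me1 rose at Fkbp5 (chromosome 17, 28398753-28517524), which encodes a co-chaperone that restrains GR. Its peaks covered 10629 ± 396 bp with LPS and 22243 ± 2127 bp with Dex+LPS in wild type, and 10457 ± 1494 bp against 24771 ± 1374 bp in Setd1aDel/+ cells (SD, n = 3 each). This was a gain of 1.12 ± 0.10 on the log2 scale (SE, limma adjusted p = 0.000305). Klf9 gained 1.25 ± 0.26 (adjusted p = 0.0316), Crispld2, a secreted protein known to be induced by glucocorticoids, 1.45 ± 0.21 (0.00482), and Ccnd3, which held one of the strongest GR sites, 1.13 ± 0.14 (0.00329). Large gains outside these lists were at the RNA helicase gene Dhx9 (2.34 ± 0.37), 4930503B20Rik (2.09 ± 0.41) and Iqck (2.07 ± 0.35). Mir1192 was listed at 0 bp in the 3 wild-type LPS libraries and at 1958 ± 608 bp with Dex+LPS. H3K4me1 fell at Mylip, which encodes a ubiquitin ligase that degrades lipoprotein receptors (−1.79 ± 0.37, adjusted p = 0.0325). Gm10863, Ppp1r16b, Scgb1a1 and Fryl were called lower too. They were listed at 0 bp in wild-type Dex+LPS libraries against 2004 ± 292, 1520 ± 807, 1697 ± 562 and 1229 ± 366 bp with LPS. Lists of wild-type Dex+LPS were cut at a −log10 q of 11.3 to 12.8 and those of wild-type LPS at 3.10 to 5.47, so weaker peaks were kept only with LPS. As deposited, the lists gave Mylip (0.087), Gm10863 (0.27) and Fryl (0.15) positive log2 values instead, and Scgb1a1 had one (0.077) with peaks within 50 kb of the TSS.

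As a group, glucocorticoid-induced genes gained H3K4me1: of 33 tested, 3 rose over all genes tested (Fkbp5, Klf9 and Crispld2), while 8 rose and 3 fell when adjusted over the list alone. The camera test placed the list above other genes (median log2 0.16, adjusted p = 0.000682 with the preset correlation and adjusted p = 0.0169 with an estimated correlation). Of 30 inflammatory genes none passed over all genes and 1 rose when adjusted over the list alone (camera adjusted p = 0.978), and of 10 interferon-stimulated genes none passed in either way (median −0.59, 0.156). Cell-cycle genes (11 tested, Ccnd3 up over all genes, 1 up and 1 down when adjusted over the list alone, 0.113) did not pass as a group. Always-named genes that did not pass were Dusp1, a phosphatase that limits MAP kinases (0.31 ± 0.09, adjusted p = 0.115), the clock gene Per1 (0.16 ± 0.16), Setd1a itself (−0.67 ± 0.38), and the inflammatory genes Nos2 (−0.43 ± 0.20), Il1b (−0.22 ± 0.23), Il6 (0.11 ± 0.20) and Ccl2 (0.15 ± 0.15). Tsc22d3, Tnf and Cxcl10 held too little H3K4me1 to be tested. Over all 7452 genes, 62 gained and 56 lost H3K4me1 (1276 at an unadjusted p under 0.05), and 113 passed with library-number series as a term. The deposited lists, where all genes shifted by +0.46 (log2 median), gave 161 gains and 0 losses by limma (3157 genes at an unadjusted p under 0.05), and lists of equal number of peaks 708 and 0 (2764 at an unadjusted p under 0.05). Wild-type libraries alone went the other way, with 26 gains and 250 losses, and Setd1aDel/+ libraries alone gave 0 of either by limma (575 at an unadjusted p under 0.05). After quantile normalization 84 gained and 17 lost. Chromosome 1 held 31 of the 56 losses (55.4%), and without it 50 genes gained and 23 lost. With single libraries left out the total ran from 45 (without Setd1aDel/+ LPS replicate 2 or 3) to 315 (97 up and 218 down, without Setd1aDel/+ Dex+LPS replicate 3).

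H3K4me2 changed at few genes with dexamethasone. Spp1, the secreted glycoprotein osteopontin (chromosome 5, 104435111-104441053), rose from 7194 ± 384 bp (n = 2) to 14063 ± 1033 bp (n = 5) in wild type and from 11401 ± 167 to 15313 ± 428 bp in Setd1aDel/+ cells (n = 3 each; log2 0.66 ± 0.05, adjusted p = 0.000148). Bach2os, an antisense transcript of Bach2 (0.87 ± 0.08), the activity-regulated gene Arc (0.55 ± 0.09) and Zbtb16, a transcription factor known to be induced by glucocorticoids (0.51 ± 0.08), also rose. Pilra and Cep192 fell. They were listed at 0 bp in all Setd1aDel/+ Dex+LPS libraries against 3407 ± 798 and 2472 ± 465 bp with LPS, and at 446 ± 997 and 0 bp against 3158 ± 564 and 1214 ± 228 bp in wild type. Stat2, which transmits interferon signals, and Slc35b1, a nucleotide sugar transporter, passed the test because the 3 Setd1aDel/+ Dex+LPS libraries listed them at 0 bp, against 2124 ± 698 and 2775 ± 315 bp with LPS. Their log2 values, with that of Pilra, were positive in the lists as deposited (Stat2 0.099, Slc35b1 0.15, Pilra 0.26).

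Klf9 (0.25 ± 0.05, adjusted p = 0.0888) and Dusp1 (0.38 ± 0.10, 0.204) came closest among the other glucocorticoid-induced genes. No gene of that list passed over all 12277 genes by limma (1847 genes at an unadjusted p under 0.05), and 4 of 30 rose when adjusted over the list alone. Camera gave an adjusted p of 0.445, against 2.65e-06 and upward in the lists as deposited. Interferon-stimulated genes lay lower as a group (25 tested, Stat2 down over all genes, 2 down when adjusted over the list alone, camera adjusted p = 0.00661, and adjusted p = 0.450 with an estimated correlation). Inflammatory genes lay lower too (32 tested, none over all genes, 1 down when adjusted over the list alone, camera adjusted p = 0.0221, and adjusted p = 0.450 with an estimated correlation, 0.709 in the lists as deposited). Housekeeping genes lay higher (17 tested, 1 up when adjusted over the list alone, 0.0221, and adjusted p = 0.562 with an estimated correlation) and did not differ detectably from other genes after quantile normalization (0.753). Values that did not pass were Fkbp5 0.15 ± 0.08, Per1 0.15 ± 0.06, Tsc22d3 −0.03 ± 0.23 (0.37 after quantile normalization), Tnf 0.13 ± 1.10, Cxcl10 −0.17 ± 0.11, Nos2 −0.74 ± 0.48, Il6 −1.53 ± 0.61, Setd1a 0.16 ± 0.08, and Il1b and Ccl2, both listed at 0 bp in Setd1aDel/+ Dex+LPS libraries. In all, 13 genes gained and 14 lost H3K4me2, and 9 passed with library-number series as a term. With single libraries left out the total of 27 ran from 14 (without wild-type Dex+LPS replicate 2) to 164 (without Setd1aDel/+ LPS replicate 3). It was 101 without wild-type LPS replicate 2 and 98 without wild-type Dex+LPS replicate 4, which stood apart from its group at 9 named genes. The split was 80 up and 6 down in the lists as deposited, whose all-gene median moved by 0.23, and 167 up and 33 down after quantile normalization, but 34 up and 108 down with no filter on covered length.

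H3K4me3 fell with dexamethasone at Cxcl10, a chemokine induced by interferon (chromosome 5, 92346638-92348889). It covered 3290 ± 102 bp with LPS and 1625 ± 84.9 bp with Dex+LPS in wild type (n = 2 each), and 2158 ± 86.5 against 1416 ± 74.1 bp in Setd1aDel/+ cells (n = 3 and 4). This was a log2 change of −0.65 ± 0.03 (adjusted p = 4.33e-05). Mir155hg, the host of the inflammatory microRNA miR-155, fell by 0.68 ± 0.04, the adaptor gene Grap by 0.66 ± 0.07 and Traf1, a signalling adaptor of TNF receptors, by 0.16 ± 0.02. C330024C12Rik was listed at 0 bp in every Dex+LPS library against 1548 ± 97.6 and 1058 ± 340 bp with LPS, and Ltbp2, a matrix protein gene, at 0 bp in Setd1aDel/+ Dex+LPS libraries. Gains were found at the cytokine receptor gene Flt3 (0.98 ± 0.08), the formin gene Inf2 (0.91 ± 0.09), the adaptor gene Sla (0.65 ± 0.07) and Dmxl1 (0.53 ± 0.05). Spsb3 passed because it was listed at 0 bp in the 3 Setd1aDel/+ LPS libraries, against 2934 ± 177 bp with Dex+LPS.

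Of 27 interferon-stimulated genes tested, none passed over all genes by limma (1048 genes at an unadjusted p under 0.05), but 13 fell and 0 rose when adjusted over the list alone (median log2 −0.34, camera adjusted p = 3.35e-15, and adjusted p = 0.144 with an estimated correlation). Inflammatory genes lay lower as well, with 2 of 29 down over all genes (Cxcl10 and Traf1) and 2 up and 8 down when adjusted over the list alone (camera adjusted p = 1.09e-06, and adjusted p = 0.104 with an estimated correlation). Glucocorticoid-induced genes lay higher (30 tested, none over all genes, 6 up when adjusted over the list alone, 0.0418, and adjusted p = 0.282 with an estimated correlation). Klf9 was at 0.13 ± 0.02 (adjusted p = 0.0542), Dusp1 at 0.19 ± 0.04, Fkbp5 at 0.18 ± 0.05, Per1 at 0.15 ± 0.04 and Tsc22d3, the anti-inflammatory leucine zipper GILZ, at 0.14 ± 0.04. These directions were the same in the lists as deposited and after quantile normalization. Nos2 (−0.49 ± 0.13), Il6 (−0.91 ± 0.34) and Setd1a (0.04 ± 0.03) did not pass, Tnf was listed at 0 bp in the 2 wild-type LPS libraries, and Il1b and Ccl2 were not tested. In all, 23 of 11977 genes gained and 25 lost H3K4me3, 37 with library-number series as a term. The split was 49 up and 23 down in the lists as deposited, but 38 up and 68 down with no filter on covered length, and 105 up and 203 down (308 in all) without wild-type Dex+LPS replicate 2.

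**Figure D2:**
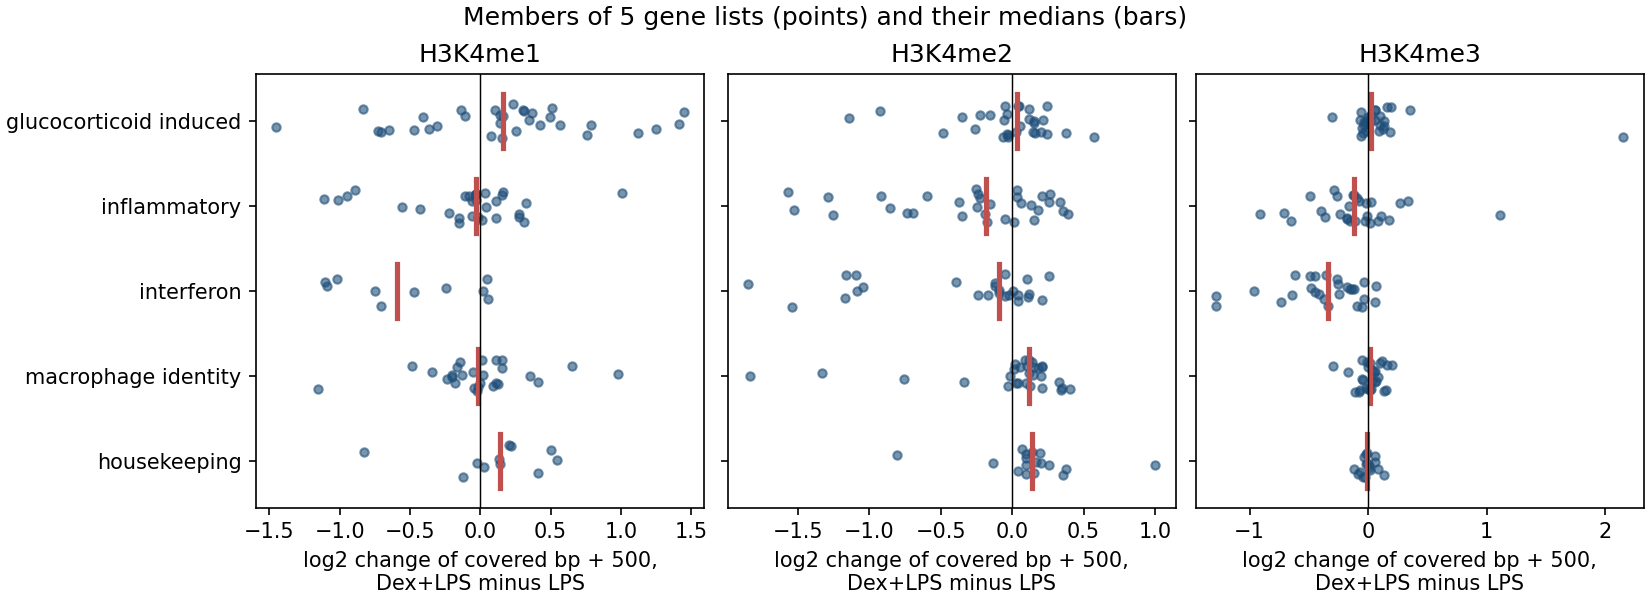
Change of covered length with dexamethasone (log2 of covered bp + 500, Dex+LPS minus LPS, averaged over genotypes) for the members of 5 gene lists (points) and their medians (bars), per mark. Interferon-stimulated genes have a median of −0.34 for H3K4me3, and glucocorticoid-induced genes one of 0.16 for H3K4me1.

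Markers of the macrophage line and of other cell types were checked alongside. With dexamethasone no member of the macrophage identity, lymphoid, non-haematopoietic or H3K4 methyltransferase complex and demethylase lists passed over all genes for any mark. Camera adjusted p for macrophage identity were 0.420 for H3K4me1, 0.130 for H3K4me2 and 0.730 for H3K4me3, and for the methyltransferase list 0.459, 0.449 and 0.287. Lymphoid markers (8, 6 and 5 tested) had 0.978, 0.449 and 0.591, but lay lower for H3K4me1 in the lists as deposited (0.00288) and after quantile normalization (0.0112). Non-haematopoietic markers, of which 4 to 6 were tested, had 0.978, 0.409 and 0.591. Housekeeping genes had 0.215 for H3K4me1 and 0.591 for H3K4me3, and cell-cycle genes 0.409 for H3K4me2 and 0.287 for H3K4me3. Adjusted over the list alone, 1 housekeeping gene rose for H3K4me1 and 1 non-haematopoietic marker for H3K4me2, and 1 lymphoid marker fell for H3K4me1. Of the cell-cycle genes 1 rose for H3K4me2, and 1 rose and 2 fell for H3K4me3.

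H3K4 methylation was compared between Setd1aDel/+ and wild-type cells. The sample titles do not say how many clones the Setd1aDel/+ libraries came from. The loss of 1 Setd1a allele therefore cannot be told apart from another difference between the cells. At Setd1a itself (chromosome 7, 127777389-127800122) H3K4me3 covered 3276 ± 110 and 3446 ± 3.54 bp in wild type (LPS, Dex+LPS) and 3264 ± 130 and 3308 ± 158 bp in Setd1aDel/+ cells. The log2 difference was −0.03 ± 0.03 (adjusted p = 0.579), with 0.06 ± 0.08 for H3K4me2 and 0.89 ± 0.38 for H3K4me1 (0.19). Peak lists carry no allele or transcript level, so these values do not check the deletion. Elsewhere the genotypes differed widely in H3K4me3. Adgrl2, an adhesion receptor gene (chromosome 3, 148815586-148989480), gained it most. It was listed at 0 bp in wild-type LPS and 138 ± 196 bp in wild-type Dex+LPS libraries, against 12071 ± 530 and 11422 ± 334 bp in Setd1aDel/+ cells. Hspb8, a small heat shock protein gene (5054 ± 720 and 5482 ± 186 bp), Olfr112, an olfactory receptor gene (4280 ± 469 and 4164 ± 554 bp), and Itga6, an integrin gene (3721 ± 79.6 and 3834 ± 158 bp), were listed at 0 bp in every wild-type library. B930018H19Rik rose by 3.15 ± 0.27 on the log2 scale. Trp53i11, a p53-induced gene (chromosome 2, 93187584-93201757), was listed at 0 bp in every Setd1aDel/+ library against 5758 ± 1679 and 6139 ± 133 bp in wild type. So were the histone gene Hist1h2ak (3081 ± 5.66 and 3336 ± 128 bp), the retinoic acid receptor gene Rarb (2356 ± 1099 and 3688 ± 521 bp), the imprinted gene Peg12 (2811 ± 436 and 2922 ± 563 bp) and Adcy2, an adenylate cyclase gene (2927 ± 184 and 2682 ± 211 bp).

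Among glucocorticoid-induced genes, H3K4me3 rose in Setd1aDel/+ cells at the phosphatase gene Dusp4 (1.07 ± 0.06), the transcription factor gene Cebpb (0.45 ± 0.05) and the cell-cycle inhibitor gene Cdkn1a (0.19 ± 0.02). It fell at Errfi1 (−0.35 ± 0.06) and Acsl1 (−0.31 ± 0.02), and was listed at 0 bp at Mertk, a receptor for the uptake of dying cells, against 1610 ± 79.2 and 2945 ± 362 bp in wild type. Counts over all genes were 7 up and 5 down of 30, and 12 and 5 when adjusted over the list alone (camera adjusted p = 0.819). Inflammatory genes went both ways, 4 up and 4 down of 29 by either adjustment (0.924). Csf2, the growth factor GM-CSF, and Cd86, a costimulatory molecule, were listed at 0 bp in wild type against 3464 ± 446 and 1589 ± 326 bp in Setd1aDel/+ LPS libraries, and Il10, an anti-inflammatory cytokine, rose by 1.29 ± 0.17. Tnf was listed at 0 bp in wild-type LPS libraries against 10332 ± 87.8 bp in Setd1aDel/+ ones. Such a switch need not be a gain of the mark, because a peak can be given to a neighbouring gene. H3K4me2 at Tnf likewise stood at 0 bp in wild-type Dex+LPS replicate 4 and at 9023 to 11262 bp in the rest of its group. Nos2, the inducible nitric oxide synthase (−0.86 ± 0.13), and Cxcl10 (−0.33 ± 0.03) fell. Of 27 interferon-stimulated genes 6 rose and 0 fell by either adjustment, among them the RNA sensor gene Ifih1 (0.67 ± 0.08), Cmpk2 (0.74 ± 0.20), Ifit2 (0.59 ± 0.10), Oas2 (0.44 ± 0.13), Trim30a (0.41 ± 0.07) and Ifnb1 (0.10 ± 0.03), with a camera adjusted p of 0.219 for the list. Macrophage identity genes had 6 up and 2 down of 28 by either adjustment (0.522), among which Csf2rb (0.50 ± 0.06), Cd14 (0.24 ± 0.04), Fcgr3 (0.20 ± 0.02) and Lyz2 (0.11 ± 0.03) rose and Adgre1, the F4/80 antigen, fell by 0.42 ± 0.03.

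H3K4me3 was compared in the remaining lists too. Of 26 genes of H3K4 methyltransferase complexes or H3K4 demethylases, Kdm5b, an H3K4 demethylase, rose by 1.14 ± 0.03 (1180 ± 43.8 to 3097 ± 62.4 bp with LPS), while Bod1 (−0.33 ± 0.04), Men1 (−0.17 ± 0.04), Kdm5a (−0.16 ± 0.05) and Kdm6a (−0.11 ± 0.03) fell, by either adjustment (camera adjusted p = 0.819). Cell-cycle genes had 5 up (Ccnd1 0.29 ± 0.02, Mki67 0.24 ± 0.04, E2f3 0.23 ± 0.06, Cdc6 0.17 ± 0.04, E2f1 0.12 ± 0.03) and 1 down (Cdk6 −0.29 ± 0.08) of 31 by either adjustment (0.522). Housekeeping genes had 5 up (among them B2m 0.35 ± 0.06, Eef2 0.22 ± 0.04, Actb 0.11 ± 0.02, Ywhaz 0.11 ± 0.02) and 1 down (Eef1a1 −0.07 ± 0.02) of 17 by either adjustment (0.219). Of the lymphoid markers Cd3e (0.12 ± 0.03) rose over all genes, with 1 up and 1 down of 5 when adjusted over the list alone (0.819). Of the non-haematopoietic ones Neurog2 (0.39 ± 0.06) and Neurod1 (0.20 ± 0.03) rose and Pdgfra fell by 0.23 ± 0.06, by either adjustment (0.522). The direction of several small values turned with the scaling. Actb (−0.11), E2f1 (−0.0024), Lyz2 (−0.050) and Cd3e (−0.092) were negative after quantile normalization. Acsl1 (0.17), Men1 (0.12), Kdm6a (0.055), Kdm5a (0.029), Cdk6 (0.29) and Eef1a1 (0.022) were positive in the lists as deposited, and Neurod1 (−0.14) and Cd3e (−0.25) were negative with peaks within 50 kb of the TSS. Fkbp5 (0.06 ± 0.05), Per1 (0.05 ± 0.04), Il6 (0.42 ± 0.34), Klf9 (0.06 ± 0.02, −0.094 after quantile normalization), Tsc22d3 (−0.09 ± 0.04) and Dusp1 (−0.08 ± 0.04) did not pass, and Tsc22d3 (0.15) and Dusp1 (0.47) were positive in the lists as deposited. Over 11977 genes, 1675 gained and 1057 lost H3K4me3 in Setd1aDel/+ cells (2564 with library-number series as a term). The split was 4008 up and 516 down in the lists as deposited, and 2213 up and 3726 down after quantile normalization.

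H3K4me2 differed between genotypes at some of the same genes. Adgrl2 covered 170 ± 240 bp in wild-type LPS and was listed at 0 bp in wild-type Dex+LPS libraries, against 13007 ± 1705 and 13107 ± 1620 bp in Setd1aDel/+ cells. Trp53i11 was listed at 0 bp in all 6 Setd1aDel/+ libraries against 11391 ± 1035 and 9514 ± 1735 bp in wild type. Gm13031 (4825 ± 222 bp in Setd1aDel/+ LPS), Gm23450 (4568 ± 2937 bp), Neo1, a netrin receptor gene (4099 ± 1147 bp), and Csf2 (2590 ± 592 bp) were listed at 0 bp in every wild-type library. Cd36, a scavenger receptor of macrophages, fell by 2.01 ± 0.26 on the log2 scale and Adgre1 by 0.36 ± 0.08. The macrophage genes Csf2rb (0.51 ± 0.12), Tlr4 (0.40 ± 0.11) and Fcgr1 (0.24 ± 0.06, but −0.015 after quantile normalization) rose. The list had 4 up and 2 down of 29 over all genes and 5 and 2 when adjusted over the list alone (camera adjusted p = 0.387). Dusp4 (0.76 ± 0.08), Fkbp5 (0.42 ± 0.08) and Cdkn1a (0.27 ± 0.04) rose among 30 glucocorticoid-induced genes (3 up over all genes, 4 up and 2 down when adjusted over the list alone, 0.751). The chemokine gene Ccl5 (0.75 ± 0.11) rose with Csf2 among 32 inflammatory genes (2 up by either adjustment, 0.876). Ifit2 (0.62 ± 0.09) and Trim30a (1.75 ± 0.46) rose among 25 interferon-stimulated genes (2 up and 1 down over all genes, 3 up and 2 down when adjusted over the list alone, 0.147), and Kdm5b (0.70 ± 0.17) among 24 methyltransferase complex and demethylase genes (1 up by either adjustment, 0.763). Irf4, a lymphoid and myeloid transcription factor (−2.73 ± 0.45), fell, and Stat2, Smim13, Trim24 and Mier1 fell and were listed at 0 bp in Setd1aDel/+ Dex+LPS libraries. B930018H19Rik rose by 3.21 ± 0.60.

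As deposited, Stat2 (0.23), Trim24 (0.55), Mier1 (0.10) and Irf4 (0.047) had positive log2 values for H3K4me2, and only Trim24 passed (adjusted p = 0.0277). Cell-cycle (31 tested), housekeeping (17), lymphoid (6) and non-haematopoietic genes (5) had no member past the threshold by limma over all 12277 genes (2631 genes at an unadjusted p under 0.05) or over the list alone. Their camera adjusted p were 0.751, 0.147, 0.876 and 0.711. Klf9 (0.03 ± 0.05), Per1 (0.13 ± 0.06), Tsc22d3 (−0.32 ± 0.23), Nos2 (−0.54 ± 0.48), Cxcl10 (−0.28 ± 0.11), Tnf (0.43 ± 1.10), Il6 (−0.23 ± 0.61, but 0.41 as deposited) and Dusp1 (0.06 ± 0.10, but −0.20 after quantile normalization) did not pass, nor did Il1b and Ccl2. In all, 508 genes gained and 325 lost H3K4me2 in Setd1aDel/+ cells (611 with library-number series as a term). In LPS libraries only 6 gained and 1 lost it, and in Dex+LPS libraries only 317 gained and 261 lost it. The split was 1588 up and 191 down in the lists as deposited, whose all-gene median moved by 0.15, and 1750 up and 1800 down after quantile normalization.

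H3K4me1 was lost in Setd1aDel/+ cells at Mertk (−1.18 ± 0.28, adjusted p = 0.0309), at Lyz2, the macrophage lysozyme (3584 ± 1313 to 1515 ± 467 bp with LPS, −1.45 ± 0.31), at Ccnd3 (−0.77 ± 0.14) and at Tlr2, a receptor for bacterial lipoproteins (−0.46 ± 0.12). The largest losses were at Gm5820 (−2.35 ± 0.36), Hdc, the histidine decarboxylase gene (−2.22 ± 0.39), Rnf144b (−2.11 ± 0.38), Usp53 (−1.91 ± 0.29) and Hmx2 (−1.82 ± 0.30). Adgrl2 (17261 ± 4188 bp in Setd1aDel/+ LPS), Hao1, a liver oxidase gene (7696 ± 1190 bp), Cers4, a ceramide synthase gene (2563 ± 471 bp), and Spaca7 (3340 ± 1464 bp) gained it and were listed at 0 bp in wild-type Dex+LPS libraries. Lists of that group were cut at the highest −log10 q (11.3 to 12.8). Rgs8, a regulator of G protein signalling, rose by 2.68 ± 0.52. Each of the glucocorticoid-induced, inflammatory, macrophage identity and cell-cycle lists had 1 member down over all genes (Mertk, Tlr2, Lyz2 and Ccnd3). Adjusted over the list alone 1, 1, 5 and 1 fell (camera adjusted p = 0.947, 0.328, 0.328 and 0.947). No member of the interferon, methyltransferase, housekeeping, lymphoid or non-haematopoietic lists passed by limma (1689 of all genes at an unadjusted p under 0.05), each with a camera adjusted p of 0.947. Fkbp5 (0.06 ± 0.10), Klf9 (0.44 ± 0.26), Dusp1 (−0.24 ± 0.09), Per1 (−0.22 ± 0.16), Il1b (−0.42 ± 0.23), Il6 (−0.09 ± 0.20), Nos2 (−0.06 ± 0.20) and Ccl2 (−0.39 ± 0.15) did not pass. Over 7452 genes, 247 gained and 168 lost H3K4me1 (360 with library-number series as a term), and 95 of the gains (38.5%) lay on chromosome 1. Without that chromosome 135 gained and 147 lost, so the excess of gains was not seen there. The split was 147 up and 288 down with peaks within 50 kb of the TSS, and 118 up and 731 down in lists of equal number of peaks. As deposited, with an all-gene median shift of −0.39, 20 gained and 144 lost, and the split was 367 and 364 after quantile normalization. The total was 191 without Setd1aDel/+ LPS replicate 2 and 739 without Setd1aDel/+ Dex+LPS replicate 2.

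Whether dexamethasone acted differently in the 2 genotypes was tested as an interaction. For H3K4me1 the treatment effect was more positive in Setd1aDel/+ cells at 101 genes and more negative at 2, but 67 of the 101 (66.3%) lay on chromosome 1 and 18 on chromosome 10. Without chromosome 1, 5 genes passed. With single libraries left out the total of 103 ran from 23 (without Setd1aDel/+ LPS replicate 1) to 336 (without Setd1aDel/+ Dex+LPS replicate 2). With the deposited lists, whose median interaction was −0.72, no gene passed by limma (1311 at an unadjusted p under 0.05). For H3K4me2 3 genes had a more positive and 12 a more negative effect, among them Stat2 and Slc35b1, listed at 0 bp only in the Setd1aDel/+ Dex+LPS group, and the median interaction of the lists as deposited was −0.22. With no filter on covered length the split turned, to 58 more positive and 17 more negative, and single libraries left out gave 7 to 50 genes. For H3K4me3 8 were more positive and 7 more negative, among them Spsb3, listed at 0 bp only in the Setd1aDel/+ LPS group, but without wild-type Dex+LPS replicate 2 these were 171 and 51. At Fkbp5 the H3K4me1 interaction was 0.19 (adjusted p = 0.892) and at Cxcl10 the H3K4me3 interaction was 0.36 (adjusted p = 0.192), so a difference of these responses between genotypes was not detectable here.

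H3K4me1 covered a smaller share of GR sites in Setd1aDel/+ cells than in wild type. In lists of equal covered length the share was 63.6 ± 6.06% against 73.5 ± 1.39% with LPS and 69.8 ± 6.92% against 75.8 ± 1.02% with Dex+LPS (n = 3 each), a mean difference of −7.92 points (exact permutation, adjusted p = 0.045 over 6 comparisons). It was −9.44 points (adjusted p = 0.0556 by the exact test) within library-number series and −11.0 points (0.0525) in the lists as deposited. Over all peaks of GR replicate 1 it was −7.30 points (0.0750) and over GR sites in all 3 libraries −5.64 points (0.120). With single libraries left out it ran from −9.67 to −6.04 points, and 7 of 12 omissions ended the call. Relative to distal H3K4me2 windows without GR, a control added later, the difference at distal GR sites was −11.1 points with equal covered length (exact permutation p = 0.02) but −1.01 points as deposited (p = 0.8 by the same exact test). H3K4me3 covered 38.9% of GR sites in Setd1aDel/+ and 50.1% in wild-type cells in lists of equal covered length (−11.3 points, adjusted p = 0.04 by exact permutation), and −11.7 points within series (0.0556). The sign turned in the lists as deposited, which are longer in Setd1aDel/+ cells: +10.4 points (0.0190). With lists of equal peak number the difference was +0.83 points (0.6).

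With dexamethasone the share of GR sites covered by H3K4me1 was 72.8% against 68.5% (+4.26 points, exact permutation adjusted p = 0.165). Relative to the distal windows it was +12 points (exact p = 0.02), but −1.21 points as deposited (exact p = 0.765). Much of the +12 points came from the windows, whose own share fell by 7.65 points at equal covered length (exact p = 0.02). For H3K4me2 it was 61.3% against 69.5% (−8.20 points, 0.165) and for H3K4me3 44.1% against 45.0% (−0.91 points, 0.724) by the same exact test. Here too the lists as deposited went the other way, with +6.57 points for H3K4me2 (adjusted p = 0.0143 by the exact test) and +4.94 points for H3K4me3 (0.0190). The H3K4me2 genotype difference was −6.35 points (0.283), and +4.42 points (0.0714) as deposited. No interaction passed by the exact permutation test: H3K4me1 p = 0.635, H3K4me2 p = 0.754, H3K4me3 p = 0.86.

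Setd1a and Cxxc1 were mapped to learn where the methyltransferase complex sits with and without dexamethasone. Cxxc1 lay at promoters: 53.2% and 56.8% of its peaks with LPS and 31.9% and 47.7% with Dex+LPS were within 1 kb of a TSS (2 libraries each). The strongest peaks found in all 4 libraries, by the authors' −log10 q, lay inside Slc39a10, a zinc transporter gene (chromosome 1, 46852550-46854233, fold 169), and across the starts of Cltc, the clathrin heavy chain gene (chromosome 11, 86756988-86758386, fold 92.7), Kmt5b, a histone H4 methyltransferase gene (chromosome 19, 3767391-3768834), Zfp607b (chromosome 7, 27688878-27689477) and Dynll1, a dynein light chain gene (chromosome 5, 115300138-115301380). Between Cltc and Kmt5b in this order came the Gm5458 region (chromosome 14, 19415725-19418905) that every library of the series marks. Setd1a peaks were fewer near promoters, 8.43% and 0.0902% with LPS and 20.7% and 3.74% with Dex+LPS. Without chromosome 1 these shares were 15.4% and 0.348%, and 32.5% and 9.44%. Its strongest recurrent peaks were 3 in the Gm5458 region (chromosome 14, 19415722-19416741, 19416923-19418986 and 19419191-19419593), and 1 each far from Fgf14 (chromosome 14, 124801583-124802219), near 4930517M08Rik (chromosome 17, 4626170-4626577) and near Celrr (chromosome 1, 120994381-120995597).

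Cxxc1 peaks lay at GR sites more often with dexamethasone. Of all Cxxc1 peaks 3.20 ± 0.348% lay at GR sites with LPS and 16.3 ± 2.18% with Dex+LPS (n = 2 each), while the number of peaks went from 13224 and 5075 to 2147 and 4472. The exact permutation test gave p = 0.333, the smallest possible for 2 against 2 libraries. Seen from the GR sites, 399 of 1519 (26.3%, 95% Wilson interval 24.1 to 28.5%) carried a Cxxc1 peak in either LPS library and 687 (45.2%, 42.7 to 47.7%) in either Dex+LPS library, against means of 0.834% and 0.285% over 100 shifts of the GR sites along their chromosomes. Single libraries covered 23.8% and 11.1% with LPS and 24.1% and 40.8% with Dex+LPS, so 1 library of each treatment covered nearly equal shares. H3K4me2 regions without GR went the other way, from 12.6% to 3.29%. At distal GR sites the share was 23.6% with LPS and 44.4% with Dex+LPS, and at distal H3K4me2 windows of equal width without GR 2.30% and 0.689%. Sites with a Cxxc1 peak in both Dex+LPS and no LPS library numbered 111, those with the opposite pattern 9, and those with a peak in all 4 libraries 91. Over all 6916 peaks of GR replicate 1 the share did not rise (29.4% with LPS and 27.2% with Dex+LPS), but relative to H3K4me2 regions without GR it was 2.33 times as high with LPS and 8.28 times with Dex+LPS. Intervals cover counting error only.

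Setd1a peaks covered 29 GR sites (1.91%) with LPS and 231 (15.2%, 95% Wilson interval 13.5 to 17.1%) with Dex+LPS, against shift means of 0.262% and 0.413%. Dex+LPS replicate 1 supplied most of these: its peaks alone covered 14.9% of GR sites and those of replicate 2 1.38%, and 9 sites carried a Setd1a peak in both Dex+LPS and no LPS library. The share of Setd1a peaks at GR sites was 0.529% and 0.180% with LPS and 3.50% and 0.649% with Dex+LPS (exact permutation p = 0.333, the smallest possible).

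**Figure D3:**
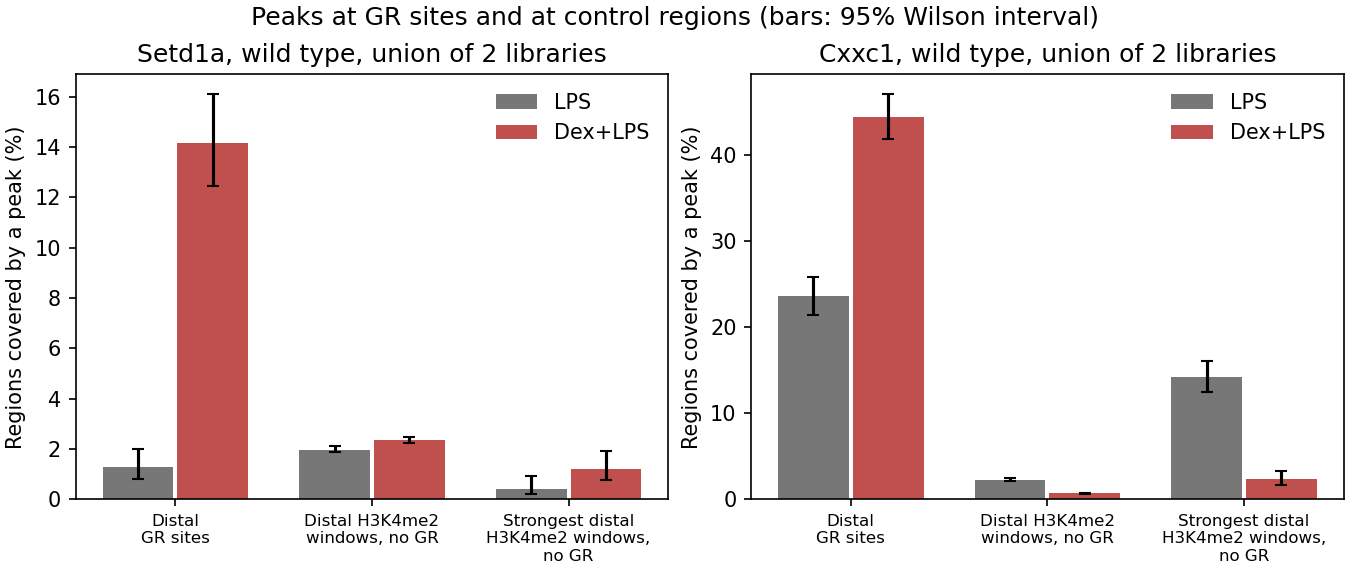
Share of distal GR sites, of distal H3K4me2 windows without GR and of the strongest such windows covered by a Setd1a or Cxxc1 peak in either of the 2 wild-type libraries per treatment (percent, bars with 95% Wilson intervals). Cxxc1 peaks cover 23.6% of distal GR sites with LPS and 44.4% with Dex+LPS, and 2.30% and 0.689% of distal H3K4me2 windows.

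Chromosome 1 held 40.3 to 74.1% of the peaks of Setd1a libraries, 14.4 to 27.9% of those of Cxxc1 and 9.73 to 12.6% of those of H3K4me1, but 6.21 to 7.63% of those of H3K4me2, H3K4me3 and GR. Chromosome 10 held more Setd1a peaks too (7.30 to 18.3%, against 5.33 to 6.72% of H3K4me2 peaks), as did chromosome 12 in single libraries (up to 8.93%). Setd1a peaks on chromosome 1 overlapped an H3K4me2 region in 0.730 to 5.27% of cases, against 28.9 to 65.0% on other chromosomes. Without chromosome 1, 19.5 ± 5.02% of Cxxc1 peaks lay at GR sites with Dex+LPS and 3.90 ± 0.683% with LPS.

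**Figure D4:**
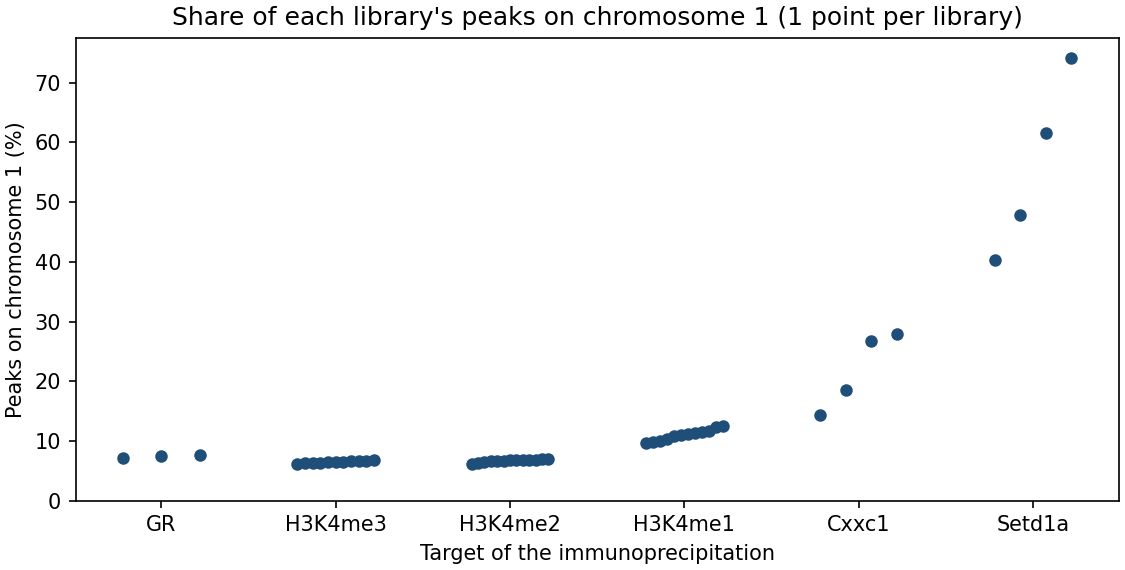
Share of each library's peaks that lie on chromosome 1 (percent, 1 point per library), by target. Setd1a libraries lie between 40.3 and 74.1%, and H3K4me3 libraries between 6.21 and 6.78%.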

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

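The tests of Setd1a at H3K4me2 regions and of the H3K4me1 interaction without chromosome 1 were chosen after the results were seen. Peaks crowd on chromosome 1 in the Setd1a (40.3 to 74.1%), Cxxc1 (14.4 to 27.9%) and H3K4me1 libraries (9.73 to 12.6%). A gain of chromosome 1 in the cells would raise its share in H3K4me2 and H3K4me3 libraries too, most among weak peaks: 18 of 24 had a larger share there, with differences of −0.787 to 2.21 points (median 0.731), which cannot tell. Setd1a binding on chromosome 1 as at its other sites is a further candidate explanation, but at most 5.27% of Setd1a peaks there met an H3K4me2 region in any library, against 28.9 to 65.0% on other chromosomes. Of 698 Setd1a peaks found in every library 558 (79.9%) lay on chromosome 1, and chromosome 10 held 7.30 to 18.3% of Setd1a peaks. Their series of library numbers hold none of the other targets, so target, preparation and sequencing run could not be told apart.

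The H3K4me1 interaction (103 genes) was marked because the treatment effect differs between genotypes. If it were a change across the genome it would remain without chromosome 1, where 5 genes passed, so that reading is not supported; of the 101 genes with a more positive effect, 67 lay on chromosome 1 and 18 on chromosome 10. Of 100 splits of the libraries 2, the real one included, gave as many genes, under the limit of 5 set before, but the highest other gave 303. The lists were also cut unevenly: the lowest −log10 q kept was 11.3 to 12.8 in wild-type Dex+LPS libraries. In the other groups it was 1.32 to 5.97, except 11.3 in Setd1aDel/+ Dex+LPS replicate 2. As deposited and after quantile normalization no gene passed by limma (1311 and 1027 at an unadjusted p under 0.05), so the part of the cut in this count cannot be told. A split that calls several times the real count points to a structure of the samples other than genotype and treatment. The count was 336 without Setd1aDel/+ Dex+LPS replicate 2.

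The H3K4me2 interaction (15 genes) was reached by 45 of 100 splits (highest other 210) and the H3K4me3 interaction (15 genes) by 64 (highest other 62), so chance cannot be excluded for either count. Single genes marked by an interaction were Stat2 (H3K4me2, −2.38, adjusted p = 0.0156), Slc35b1 (H3K4me2, −2.19, adjusted p = 0.0239) and Spsb3 (H3K4me3, 2.69, adjusted p = 5.13e-07). With peaks within 50 kb of the TSS, which do not depend on the nearest gene, the interactions numbered 0 for H3K4me2 (489 at an unadjusted p under 0.05 in limma) and 3 for H3K4me3. By Dixon's test at 0.05, which by chance sets apart about 1 in 20 groups, 12 of 130 values tested stood apart, against 6.5 by chance. Replicate 4 of H3K4me2 wild-type Dex+LPS supplied 9 of them: B930018H19Rik 2663 bp, Ccl5 3206 bp, Cdkn1a 6841 bp, Il1b 1836 bp, Il6 1400 bp, Per1 7532 bp, Pilra 2229 bp, Tnf 0 bp and Trp53i11 12493 bp. The others were Dusp4 (16496 bp) in replicate 3 of the same group, and Cd86 (0 bp) in replicate 1 and Il10 (2234 bp) in replicate 2 of H3K4me3 Setd1aDel/+ Dex+LPS. Only groups of 4 or more libraries could be tested, which were H3K4me2 wild-type Dex+LPS and H3K4me3 Setd1aDel/+ Dex+LPS. No library-wide measure stood apart in these. H3K4me1 groups were not tested: replicate 2 of Setd1aDel/+ Dex+LPS covered 70.7 Mb, against 32.6 and 32.9 Mb in replicates 1 and 3.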

How the results depend on the processing

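Quantile normalization, leaving out chromosome 1, the block in wild-type libraries alone, the covered length interaction without single libraries, the distal H3K4me2 windows and the tests of the turn in GR share were chosen after the results were seen. Among the other settings of the comparisons, 341 kept direction and side of the threshold (counts within 1.5 times), 31 ended a call, 2 made one, 120 moved a count or share further and 11 reversed a direction. With a pseudocount of 100 bp totals stayed within 1.5 times, but H3K4me1 treatment had 58 genes up and 113 down, against 62 and 56, and its interaction 144 genes. Shares of GR sites kept direction and side of the threshold with distal GR sites and with GR sites outside chromosome 1, as did the Setd1a and Cxxc1 shares of GR sites within 500 bp. Gene list tests kept theirs in 198 of 216 settings and named genes in 3639 of 4238, where 29 of 178 results reversed in at least 1 setting. Where no cause is given, the cause was not tested. Settings with 1 genotype or treatment use fewer libraries. The number of reads is not given in the sources used here, so no result could be adjusted for depth. In simulated H3K4me1 lists, changes of 1 (log2) were recovered in 43.3% of genes for treatment, so many changes may go unseen.

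For the share of GR sites covered, the settings give these differences in points, with adjusted exact permutation p in brackets. In the lists as deposited, H3K4me1 genotype was −11.0 (0.0525), H3K4me2 treatment 6.57 (0.0143), H3K4me2 genotype 4.42 (0.0714), H3K4me3 treatment 4.94 (0.0190) and H3K4me3 genotype 10.4 (0.0190). In lists of equal number of peaks, H3K4me2 treatment was 6.61 (0.0143), H3K4me2 genotype 2.32 (0.373), H3K4me3 treatment 3.38 (0.0643) and H3K4me3 genotype 0.828 (0.60). With an overlap of at least 50% of the GR site, H3K4me3 treatment was 1.85 (0.143). With labels permuted within library-number series, H3K4me1 genotype was −9.44 (0.0556) and H3K4me3 genotype −11.7 (0.0556). H3K4me1 genotype was −7.30 (0.0750) over all peaks of GR replicate 1 and −5.64 (0.120) over GR sites in all 3 libraries. Over all settings, libraries left out included, these adjusted p ran from 0.0200 to 0.135 for H3K4me1 genotype, from 0.0143 to 0.500 for H3K4me2 treatment, from 0.0714 to 0.60 for H3K4me2 genotype, from 0.0190 to 0.878 for H3K4me3 treatment and from 0.0190 to 0.60 for H3K4me3 genotype. The covered length of H3K4me1 with treatment was 17.9 Mb within series (exact p = 0.0972), and its number of peaks, counted in units of 1000, 15.3 higher (exact p = 0.280), with an unadjusted range of 0.0250 to 0.280 over all settings.

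The GR share turned with the way lists are made equal. Equal covered length may keep fewer peaks where peaks are wide, and H3K4me2 may be lost at GR sites with dexamethasone. Among LPS libraries alone, those that kept 37283, 30326, 22694, 19046 and 16166 H3K4me2 peaks covered 80.7, 78.0, 66.2, 61.2 and 57.1% of GR sites. The share thus fell with the number of peaks kept even without dexamethasone. Whether H3K4me2 is also lost at GR sites with dexamethasone cannot be told here. The H3K4me2 treatment difference was 6.61 points with lists of equal number of peaks and 6.57 points in the lists as deposited, but both kinds of list are longer with dexamethasone (73.0 against 61.8 Mb and 78.4 against 65.4 Mb), which raises the share either way. Against distal H3K4me2 windows of equal width, the H3K4me3 genotype difference at GR sites was also 5.93 points as deposited and −7.32 points with equal covered length (exact permutation p = 0.00667 for each, the smallest they can give).

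Counts of genes changed moved as follows. In the lists as deposited: H3K4me1 genotype 164 and interaction 0 (1311 genes at an unadjusted p under 0.05 in limma), H3K4me2 treatment 86, genotype 1779 and interaction 6, H3K4me3 genotype 4524. In lists of equal number of peaks: H3K4me1 treatment 708 (all up), genotype 849 (118 up and 731 down) and interaction 1, H3K4me2 treatment 79, genotype 1642 and interaction 7. After quantile normalization: H3K4me1 genotype 731 and interaction 0 (1027 genes at an unadjusted p under 0.05 in limma), H3K4me2 treatment 200, genotype 3550 and interaction 7, H3K4me3 treatment 95 and genotype 5939. With no filter on covered length: H3K4me2 treatment 142 (34 up and 108 down) and interaction 75 (58 and 17), H3K4me3 treatment 106 (38 and 68) and interaction 56 (38 and 18). With peaks within 50 kb of the TSS: H3K4me1 interaction 2, H3K4me2 interaction 0 (489 genes at an unadjusted p under 0.05 in limma), H3K4me3 genotype 4493 and interaction 3. With a pseudocount of 2000 bp: H3K4me1 interaction 32 and H3K4me2 interaction 8. With library-number series as a term: H3K4me2 treatment 9 and interaction 2. Without chromosome 1: H3K4me1 treatment 73 and interaction 5. In wild-type libraries only, H3K4me1 treatment was 276 (26 up and 250 down). In Setd1aDel/+ libraries only, treatment was 0 for H3K4me1 (575 genes at an unadjusted p under 0.05 in limma), 2 for H3K4me2 and 21 for H3K4me3. In LPS libraries only, genotype was 4 for H3K4me1, 7 for H3K4me2 and 1287 for H3K4me3. In Dex+LPS libraries only it was 55 for H3K4me1 and 1265 for H3K4me3. Main counts were 118, 415 and 103 for H3K4me1 (treatment, genotype, interaction), 27, 833 and 15 for H3K4me2, and 48, 2732 and 15 for H3K4me3.

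Of 9 gene lists, the number that passed with treatment for H3K4me1 was 1, and 2 in the lists as deposited and after quantile normalization, where lymphoid markers lay lower than other genes (camera adjusted p = 0.00288 and 0.0112). With an estimated correlation 0 lists passed in camera for H3K4me2 treatment (0 at an unadjusted p under 0.05) and 0 for H3K4me3 treatment (2 at an unadjusted p under 0.05), against 3 for each with the preset one. For H3K4me2 genotype 1 list passed as deposited, against 0 (2 at an unadjusted p under 0.05 in camera). Housekeeping genes did not differ detectably from others for H3K4me2 with treatment after quantile normalization (0.753). H3K4me1 losses nearest to GR sites were 11.8% after quantile normalization and 7.50% with peaks within 50 kb of the TSS, against 1.79%.

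Shares of Cxxc1 peaks at GR sites differed by 18.0 points with a −log10 q of at least 5 and by 15.6 points without chromosome 1, against 13.1 points. With sites found in both libraries of a group, Setd1a covered 0.197% (LPS) and 1.12% (Dex+LPS) of GR sites and Cxxc1 8.95% and 19.4%. Over all peaks of GR replicate 1, Setd1a covered 11.4% with Dex+LPS, and Cxxc1 29.4% with LPS and 27.2% with Dex+LPS. At distal GR sites Setd1a covered 1.27% and Cxxc1 23.6% with LPS.

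Named genes whose log2 value changed sign were these. Treatment, lists as deposited: Gm10863 0.27, Fryl 0.15 and Mylip 0.087 for H3K4me1, Stat2 0.099, Pilra 0.26 and Slc35b1 0.15 for H3K4me2. Treatment, equal number of peaks: Fryl 0.12, Stat2 0.10, Pilra 0.30 and Slc35b1 0.15. Treatment, other settings: Scgb1a1 0.077 with peaks within 50 kb of the TSS, Tsc22d3 0.37 and Pilra 0.017 for H3K4me2 after quantile normalization, and Stat2 0.027 in wild-type libraries only. Genotype, H3K4me2, lists as deposited: Il6 0.41, Stat2 0.23, Trim24 0.55, Mier1 0.10 and Irf4 0.047. Equal number of peaks: Il6 0.38, Stat2 0.16, Trim24 0.32 and Mier1 0.10. Quantile normalization: Dusp1 −0.20, Il6 0.21, Stat2 0.068, Fcgr1 −0.015 and Trim24 0.33. In LPS libraries only Stat2 was 0.091. Genotype, H3K4me3, lists as deposited: Tsc22d3 0.15, Dusp1 0.47, Acsl1 0.17, Men1 0.12, Kdm6a 0.055, Kdm5a 0.029, Cdk6 0.29 and Eef1a1 0.022. Equal number of peaks: Tsc22d3 0.14, Dusp1 0.29, Acsl1 0.12, Men1 0.12, Kdm6a 0.013 and Cdk6 0.13. Quantile normalization: Dusp1 0.31, Klf9 −0.094, Acsl1 0.074, Lyz2 −0.050, Men1 0.0076, E2f1 −0.0024, Cdk6 0.086, Actb −0.11 and Cd3e −0.092. Peaks within 50 kb of the TSS: Men1 0.0034, Cd3e −0.25 and Neurod1 −0.14.

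Leaving out 1 library at a time gave these ranges; a group left with 1 library is assumed to vary like the others in limma. H3K4me1 covered length with treatment ran from 12.8 to 22.4 Mb and lost its unadjusted exact p under 0.05 in 9 of 12 omissions: wild-type LPS replicates 1 (18.8), 2 (21) and 3 (17.6), wild-type Dex+LPS replicates 1 (18.7), 2 (19.2) and 3 (19.6), Setd1aDel/+ LPS replicates 2 (16.7) and 3 (19.6), and Setd1aDel/+ Dex+LPS replicate 2 (12.8). The H3K4me1 genotype difference in GR share ran from −9.67 to −6.04 points and lost its call without any wild-type library (LPS −7.89, −8.28 and −7.59, Dex+LPS −7.65, −8.16 and −7.95 for replicates 1 to 3) or Setd1aDel/+ Dex+LPS replicate 3 (−6.04). H3K4me2 covered length with treatment ran from 9.82 to 16.0 Mb and had an unadjusted exact p under 0.05 without wild-type Dex+LPS replicate 4 (14.9) or Setd1aDel/+ LPS replicate 3 (15.3), but not after adjustment (0.0800 and 0.0571). The H3K4me3 treatment difference in GR share ran from −3.89 to 2.07 points, turning without wild-type LPS replicate 2 (1.35) and wild-type Dex+LPS replicate 1 (2.07). The H3K4me3 genotype difference ran from −14.2 to −8.28 points and lost its call without each wild-type library (LPS replicates 1 and 2 −13.1 and −11.3, Dex+LPS replicates 1 and 2 −14.2 and −8.28), where fewer permutations remain.

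Gene counts without 1 library ran as follows. H3K4me1 treatment, 45 to 315: wild-type LPS replicates 1 (75), 2 (67) and 3 (48), wild-type Dex+LPS replicates 1 (179) and 3 (74), Setd1aDel/+ LPS replicates 1 (65), 2 (45) and 3 (45), Setd1aDel/+ Dex+LPS replicates 1 (61) and 3 (315). H3K4me1 genotype, 191 to 739: wild-type LPS replicates 2 (244) and 3 (215), Setd1aDel/+ LPS replicates 1 (236), 2 (191) and 3 (212), Setd1aDel/+ Dex+LPS replicates 2 (739) and 3 (260). H3K4me1 interaction, 23 to 336: wild-type LPS replicates 1 (36), 2 (29) and 3 (32), wild-type Dex+LPS replicate 3 (57), Setd1aDel/+ LPS replicates 1 (23), 2 (58) and 3 (34), Setd1aDel/+ Dex+LPS replicates 1 (39), 2 (336) and 3 (60). H3K4me2 treatment, 14 to 164: wild-type LPS replicate 2 (101), wild-type Dex+LPS replicates 2 (14) and 4 (98), Setd1aDel/+ LPS replicates 1 (53) and 3 (164), Setd1aDel/+ Dex+LPS replicate 2 (67). H3K4me2 genotype, 517 to 1230: wild-type LPS replicate 1 (517). H3K4me2 interaction, 7 to 50: wild-type LPS replicate 2 (47), wild-type Dex+LPS replicates 2 (7), 3 (7) and 4 (50), Setd1aDel/+ LPS replicates 1 (38) and 3 (47), Setd1aDel/+ Dex+LPS replicates 2 (47) and 3 (28). H3K4me3 treatment, 42 to 308: wild-type Dex+LPS replicate 2 (308) and Setd1aDel/+ LPS replicate 3 (100). H3K4me3 interaction, 20 to 222: wild-type LPS replicates 1 (34) and 2 (26), wild-type Dex+LPS replicates 1 (38) and 2 (222), Setd1aDel/+ LPS replicates 1 (25), 2 (23) and 3 (49), Setd1aDel/+ Dex+LPS replicate 4 (25). With 1 library per group, Setd1a covered 0.197% (without LPS replicate 1) to 1.91% and 1.38% (without Dex+LPS replicate 1) to 14.9% of GR sites. Cxxc1 covered 11.1% (without LPS replicate 1) to 23.8% and 24.1% (without Dex+LPS replicate 2) to 40.8%.

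With the replicate number as a replicate block, genes changed numbered 94, 378 and 75 for H3K4me1 (treatment, genotype, interaction), 151 (31 up and 120 down), 685 and 100 (80 and 20) for H3K4me2, and 35, 2252 and 14 for H3K4me3, and 1 list passed for H3K4me3 genotype (interferon genes, adjusted p = 0.000195), against 0 (2 at an unadjusted p under 0.05 in camera). The block also ended the call of 2 gene lists with treatment (inflammatory genes for H3K4me2, glucocorticoid-induced genes for H3K4me3) and of 21 of 178 named-gene results, and reversed none. Whether an effect itself differs under the block was not tested. In it the covered length differed by 19.2 Mb (H3K4me1 treatment, exact p = 0.125) and 4.91 Mb (H3K4me3 genotype, 0.125), and the GR share by −7.92 points (H3K4me1 genotype, 0.0938) and −11.0 points (H3K4me3 genotype, 0.250), where few permutations are possible. For H3K4me2 genotype the differences were 3.11 Mb and −1.55 points, against 11.3 Mb and −6.35 points.

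Whether the numbers pair the libraries depends on the groups compared. Of the wild-type H3K4me1 libraries, LPS against Dex+LPS, all 3 same-numbered pairs had deviations that correlated by over 0.1 (0.479, 0.159 and 0.136), though only 2 of 6 libraries correlated best with their own number. With the replicate block in these libraries alone, 22 genes gained and 158 lost H3K4me1 (180 in all), against 26 and 250 without it. The same pairs of Setd1aDel/+ libraries correlated by 0.170, −0.136 and 0.0572, so the treatment effect averaged over genotypes was not taken as paired. Over all marks and groups 7 of 46 pairs were over 0.1, and correlations ran from −0.136 to 0.479 for H3K4me1, −0.289 to 0.248 for H3K4me2 and −0.141 to 0.132 for H3K4me3.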

Other observations

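The tests of genes nearest to GR sites, the overlaps between marks, and the test of more Cxxc1 calling were chosen after the results were seen. Genes that gained H3K4me1 with dexamethasone were mostly those nearest to a GR site: 46 of 62 (74.2%), against 14.8% of all 7452 genes (odds ratio 17.3, Fisher adjusted p = 7.92e-25 over 12 sets), and 1 of 56 genes that lost it (1.79%, adjusted p = 0.00513). After quantile normalization the share of losses was 11.8% (Fisher adjusted p = 0.740), and 31 of the 56 losses lay on chromosome 1. With peaks within 50 kb of the TSS it was 7.50%, against 8.72% of all genes, so the deficit was not seen there. For H3K4me3 gains it was 7 of 23 (30.4% against 8.87%, adjusted p = 0.00582), and for H3K4me2 gains 3 of 13 (adjusted p = 0.166). In the lists as deposited the shares of gains were 41.6% for H3K4me1, 31.3% for H3K4me2 and 42.9% for H3K4me3. With genotype, 88 of 508 H3K4me2 gains (17.3%, Fisher adjusted p = 1.59e-08) lay nearest to a GR site, against 9.20% of all genes tested. So did 189 of 1675 H3K4me3 gains (11.3%) and 154 of 1057 H3K4me3 losses (14.6%), against 8.87% of all, the losses 4.46% in the lists as deposited. Gene length was not adjusted for.

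H3K4me2 and H3K4me3 differed between genotypes at shared genes: 303 gained both (65.6 expected by chance) and 143 lost both (23.2 expected), while 7 and 6 went opposite ways (40.6 and 37.5 expected). H3K4me1 and H3K4me3 shared 55 gains (26.4 expected) and 28 losses (15.7 expected), and H3K4me1 and H3K4me2 35 gains (8.83 expected) and 10 losses (3.95 expected). With dexamethasone 3 genes, Hs1bp3 and Zbtb16 among them, gained H3K4me1 and H3K4me2 (0.0871 expected), and Bach2os, Flt3 and Spp1 H3K4me2 and H3K4me3 (0.0215 expected). Hs1bp3 was chosen after its values were seen.

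More or stronger calling of Cxxc1 peaks with dexamethasone is a candidate explanation, but distal H3K4me2 windows without GR were covered at 0.689%, down from 2.30% with LPS. Strong chromatin marks at GR sites are another, but the strongest such windows were covered at 2.34%, down from 14.2%. Regions with very high pileup are a further one, but only 14 of 1519 GR sites have a pileup over 1000, and at the other 1505 the number covered still went from 397 to 685 (26.4% to 45.5%). By these values none of the 3 accounts for the difference, but the windows lie at the middle of H3K4me2 regions and match GR sites only in part. The difference rests on 2 libraries per treatment, of which 1 each covered nearly equal shares of GR sites (23.8% with LPS, 24.1% with Dex+LPS). Over all peaks of GR replicate 1 it was seen only relative to H3K4me2 regions without GR.

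Splits of the libraries show where chance can be excluded for the other gene counts, the real split being 1 of 100. For genotype no other split gave as many genes: 415 against at most 113 for H3K4me1, 833 against 286 for H3K4me2 and 2732 against 176 for H3K4me3, so 1 of 100 in each. Splits cannot tell the lost allele from another difference between the cells. For H3K4me3 treatment 3 of 100 gave 48 or more (highest other 56). For H3K4me1 treatment 5 of 100 gave 118 or more, so chance cannot be excluded. The highest other gave 347, but it exchanged only Setd1aDel/+ LPS replicate 1 and Setd1aDel/+ Dex+LPS replicate 3. It lies near the real split and does not show a structure of the samples other than genotype and treatment. For H3K4me2 treatment 20 of 100 gave 27 or more (highest other 141), so chance cannot be excluded. The split with 141 switched the treatment labels of all Setd1aDel/+ libraries together, which leaves their 2 groups intact, so it does not show such a structure either.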
